A study of Mus musculus with 8 samples.

How the data were processed

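RNA-seq was made from hippocampal CA1 tissue of C57BL/6 mice of 2 months, per the labels, with Trizol extraction and a stranded mRNA library kit. The labels give 4 WT and 4 cKO libraries, while a protocol speaks of 3 pairs of mice, and which libraries came from which mice is not given in the sources used here. Per the submitters' processing notes, STAR, StringTie and DESeq2 were used, with no versions, and the genome build was mm9. The roles of these tools, the annotation, the strand setting of the counting and the exons removed in the knockout are not given in the sources used here. Many gene identifiers in the table are newer than that build, and the reference at hand is of a later build (GRCm38), so no coordinates are printed. NCBI's gene table for GRCm38.p6 served only to find which genes neighbour each other.

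The authors deposited 1 table of 34094 genes with a log2 value per library. Each deposited log2 value equals log2(reads / size factor + 1), since 2 to the power of the value, minus 1, is a whole multiple of 1 step per library for 100% of values (tolerance 0.001 reads). Multiplying out these steps gave back the read counts, and the sum over genes gave the depth of each library. The deposited table also holds the authors' log2 fold change, p-value and FDR for cKO against WT. That fold change equals the difference of group means, and the FDR equals the Benjamini-Hochberg adjustment of the deposited p-value over the 34094 genes. The test behind the p-value is not stated beyond the tool names. The 2 columns of group means were not used. Gene symbols came from the table, in which 1552 genes have none.

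The main test compared the 4 cKO with the 4 WT libraries by limma 3.58.1 in R 4.3.3 on the deposited log2 values (pseudocount 1, mean-variance trend, robust estimation, no covariate), for the 26135 genes with a normalized value of at least 1 in at least 4 libraries. A count test had been planned for raw counts. The table holds log2 values, so the planned fallback, limma-trend, was the main test, and limma-voom on the recovered reads was added after seeing the data. Adjusted p is Benjamini-Hochberg throughout, with a threshold of 0.05. Gene lists were tested with camera (preset correlation 0.01), with camera with an estimated correlation, and with fry. Of 41 lists fixed before the data were examined, 40 had at least 5 tested members and 1, the sex-linked genes, had fewer and was not tested. A list of nuclear-retained transcripts and a list of hindbrain and spinal markers were chosen after seeing the data. Single values were compared by a two-sided exact permutation test over all splits, which for 4 against 4 gives no p below 0.0286. All 35 splits of the 8 libraries into 4 and 4 were refitted to see how often other groupings give as much. A floor of 3 reads over a group stands for a group with no reads, and floors cover counting error only.

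Named genes were chosen by a rule set before the data were examined. It takes Brpf1 and the measured members of the list of BRPF1 complexes and related genes. It then takes genes past the main test with a mean log2 value of at least 1, a regular symbol and no overlap between groups, up to 12 in each direction. It also takes up to 4 members, by adjusted p, of every list that passes camera. As few genes passed, the same rule was also applied to the FDR of the authors' deposited table, a choice made after seeing the data. The text names a part of the genes so chosen.

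The procedure was tested on simulated data for cKO against WT, 4 against 4, over 27781 genes. limma recovered 38% of 50 genes raised 1.5-fold, 98% of 50 genes raised 3-fold, 78% of 50 genes lowered to 0.5 of their level and 98% of 50 genes lowered to 0.25, and called 6 unchanged genes. The raised and lowered genes were drawn only from genes with many reads on average. The shares recovered therefore do not cover genes with few reads, such as Hoxc4 and Tlx1. camera found the shifted list and called 0 of 40 unshifted ones. The simulated genes were drawn independently of each other. The simulation therefore does not show how often camera falsely calls lists whose members vary together, as those of several real lists do. Alternatives were quantile normalization, no filter and a stricter one, a pseudocount of 0.1, array weights, a replicate block, other thresholds, camera with an estimated correlation, and leaving out each library in turn. A covariate for choroid plexus content was added after seeing the data. Figures were drawn with matplotlib 3.10.9.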

Results

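RNA from the CA1 field of the mouse hippocampus was sequenced from wild-type (WT) mice and from mice with a conditional knockout (cKO) of Brpf1, a gene linked to intellectual disability whose product is a scaffold of histone acetyltransferase complexes. The animals were C57BL/6 mice of 2 months, and each group holds 4 libraries. The sample titles read hippocampus tissue, without naming CA1, and label the cKO samples as cko type (Brpf1 knockdown). Reads on genes ranged from 42346644 to 49897832 per WT library and from 40330226 to 46559795 per cKO library, a difference within the spread between libraries (two-sided exact permutation p = 0.286). Values below are normalized reads, meaning reads divided by the library's size factor, and fold changes are on the log2(normalized reads + 1) scale, which understates the change of genes with few reads. Between any pair of libraries the Pearson correlation of these log2 values across genes lay between 0.967 and 0.982. The labels do not say which mouse each library came from, so the p-values below measure the spread between these libraries, which may be partly technical.

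The targeted gene, Brpf1 (ENSMUSG00000001632), was lower in all 4 cKO libraries than in any WT library, with 945 ± 87.3 normalized reads (SD, n = 4) against 1415 ± 55.1, or 66.8% of the WT level. The exact permutation p of 0.0286 is the smallest that 4 libraries against 4 can give. The log2 fold change was −0.59 (SE 0.089), with a limma adjusted p of 0.132 (Benjamini-Hochberg over 26135 genes), so Brpf1 did not pass the test across all genes. That adjusted p ranged from 0.0619 to 0.484 over the alternative settings. The authors' deposited table gives Brpf1 an FDR of 1.47e-07. The exons removed are not given in the sources used here, so gene-level reads do not separate intact from deleted transcript.

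No other gene in the list of BRPF1 complexes and related genes passed the test. Kat6a and Kat6b, which encode acetyltransferases that BRPF1 joins, had 3370 ± 301 and 3004 ± 124 normalized reads in WT against 3461 ± 445 and 2951 ± 259 in cKO (SD, n = 4). The paralogs Brd1 and Brpf3 had 2132 ± 249 and 954 ± 132 in WT against 2179 ± 167 and 954 ± 156 in cKO. Log2 fold changes were 0.26 (SE 0.10) for Kat7, 0.26 (SE 0.13) for Jade2, 0.24 (SE 0.11) for Jade1 and 0.21 (SE 0.074) for Meaf6, none of which passed limma over all genes. Jade3, Ing4 and Ing5 had log2 fold changes of 0.081 (SE 0.26), 0.052 (SE 0.089) and −0.0022 (SE 0.10). As a list of 12 genes the complexes did not pass camera, which compares them with other genes (adjusted p = 0.326), but passed fry's test for change in either direction (adjusted p = 0.00101), and Brpf1 was the 1 member past the threshold adjusted over the list alone.

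Across all genes, cKO CA1 differed from WT at 5 genes. The transcription factor gene Pax2 (ENSMUSG00000004231), which acts in embryonic midbrain, hindbrain and kidney, rose 20.1-fold, from 19.5 ± 9.70 to 393 ± 170 normalized reads (SD, n = 4). St6gal2 (ENSMUSG00000024172), which encodes a sialyltransferase, rose 3.37-fold, from 1188 ± 42.8 to 4000 ± 988. Aasdhppt (ENSMUSG00000025894), whose product attaches phosphopantetheine to carrier proteins, fell to 43.9% of the WT level, from 1639 ± 87.1 to 719 ± 72.6. Robo3 (ENSMUSG00000032128), an axon guidance receptor, fell to 45.4%, from 1296 ± 190 to 589 ± 71.1, and the carbonyl reductase gene Cbr1 (ENSMUSG00000051483) fell to 55.1%, from 1528 ± 96.3 to 842 ± 52.0.

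**Figure D1:**
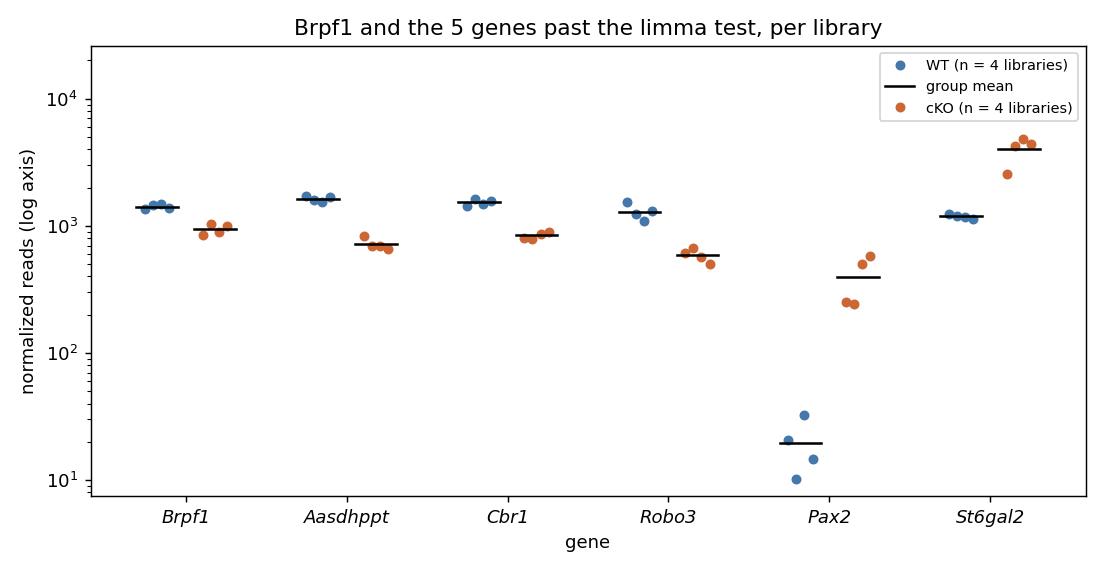
Normalized reads (log axis) of Brpf1 and of the 5 genes past the limma test in each library, with WT in blue, cKO in orange, 4 libraries each, and a black bar at the group mean. For every gene shown the groups do not overlap, and Pax2 shows the widest gap, with means of 19.5 in WT and 393 in cKO.

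The log2 fold changes of these genes in limma were 4.27 for Pax2 (SE 0.39, adjusted p = 0.00586), 1.71 for St6gal2 (SE 0.17, adjusted p = 0.00660), −1.19 for Aasdhppt (SE 0.094, adjusted p = 0.00260), −0.86 for Cbr1 (SE 0.086, adjusted p = 0.00660) and −1.13 for Robo3 (SE 0.13, adjusted p = 0.0168). At an unadjusted p under 0.05, 2266 of the 26135 genes tested passed (8.67%), 1063 higher and 1203 lower in cKO. The groups did not overlap at 1285 genes (4.92%), where chance gives 2.86%. Aasdhppt passed under all 16 alternative settings. Robo3 passed under 9 of them and lost its call without WT replicate 2 or 4 or cKO replicate 1, 3 or 4 (adjusted p from 0.0577 to 0.105) or with a choroid plexus covariate (0.0664). Cbr1 lost its call without WT replicate 4 (adjusted p = 0.0548), and Pax2 did not pass limma-voom on the recovered reads (adjusted p = 0.148). With the replicate block Cbr1, Robo3 and St6gal2 also lost their calls (adjusted p = 0.125, 0.125 and 0.107).

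The authors' deposited table lists 224 genes at an FDR under 0.05, 120 of them higher in cKO and the rest lower, and the 5 genes above are among them. Of the 224, 214 were tested here, and all 214 had an unadjusted limma p under 0.05. Of the 224, 7 had reads in 1 library only. Genes that the authors' deposited table calls and limma does not include the membrane protein genes Cxadr, with 344 ± 63.7 normalized reads in WT and 1387 ± 731 in cKO (SD, n = 4), and Stoml3, with 65.6 ± 7.51 and 29.1 ± 3.45. Cxadr passed limma without cKO replicate 3 (adjusted p = 0.0313). Further genes lower in cKO in that table were Ikzf2 (334 ± 23.9 against 148 ± 84.8), Dnah3, an axonemal dynein gene (90.3 ± 34.4 against 28.6 ± 9.53), Smim5 (72.6 ± 19.6 against 23.8 ± 6.99) and Fst, which encodes the activin-binding protein follistatin (75.4 ± 22.2 against 28.7 ± 12.1).

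Genes for developmental transcription factors had the largest median difference of the 40 lists tested. The list of Hox and other developmental regulators rose as a whole in camera (26 members tested, 18 with a positive log2 fold change, median 0.90, adjusted p = 7.20e-06), though not with an estimated correlation (adjusted p = 0.196 with an estimated correlation, unadjusted p = 0.00731). No member passed limma over all genes, and 8 members passed adjusted over the list alone, all 8 of them higher in cKO. In 6 of the 26 every cKO library was above every WT library, where chance gives 1.43%. Foxd1 had 54.0 ± 8.27 normalized reads in WT and 220 ± 89.7 in cKO (log2 fold change 1.93, SE 0.28, limma adjusted p = 0.102, but 0.0380 without cKO replicate 1). Twist1 had 51.2 ± 17.2 and 180 ± 46.4 (log2 fold change 1.81, SE 0.28, limma adjusted p = 0.153), and Hoxa7 had 28 reads over the 4 WT libraries and 189 over the 4 cKO libraries, 6.86-fold more in normalized reads.

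Several genes of this kind had almost no reads in WT. Hoxc4 had 2 reads over the 4 WT libraries and 115 over the 4 cKO libraries, and Hoxc6 had 6 and 115. Tlx1 (ENSMUSG00000025215), a homeobox gene, had 0 reads in WT and 96 in cKO, at least 33.4-fold higher against a floor of 3 reads over the WT group (limma adjusted p = 0.0714). With array weights Hoxc4 and Tlx1 passed limma over all genes (adjusted p = 0.0494 for each). The paired box gene Pax1 likewise had 0 reads in WT and 51 in cKO, at least 18.3-fold higher (limma adjusted p = 0.213). Summed over all 29 Hox genes listed, normalized reads were 58.1 ± 77.1 in WT and 234 ± 108 in cKO (SD, n = 4, exact permutation p = 0.0857), with 173 in WT replicate 1 alone. That library also held 61 reads of 4 Y-linked genes, while no other library held more than 9. Its normalized reads of Xist, which is expressed in female cells, were 62066, within the 61454 to 71044 of the other WT libraries. The Y-linked reads therefore do not mark it as a library from a male alone, and their source was not tested.

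**Figure D2:**
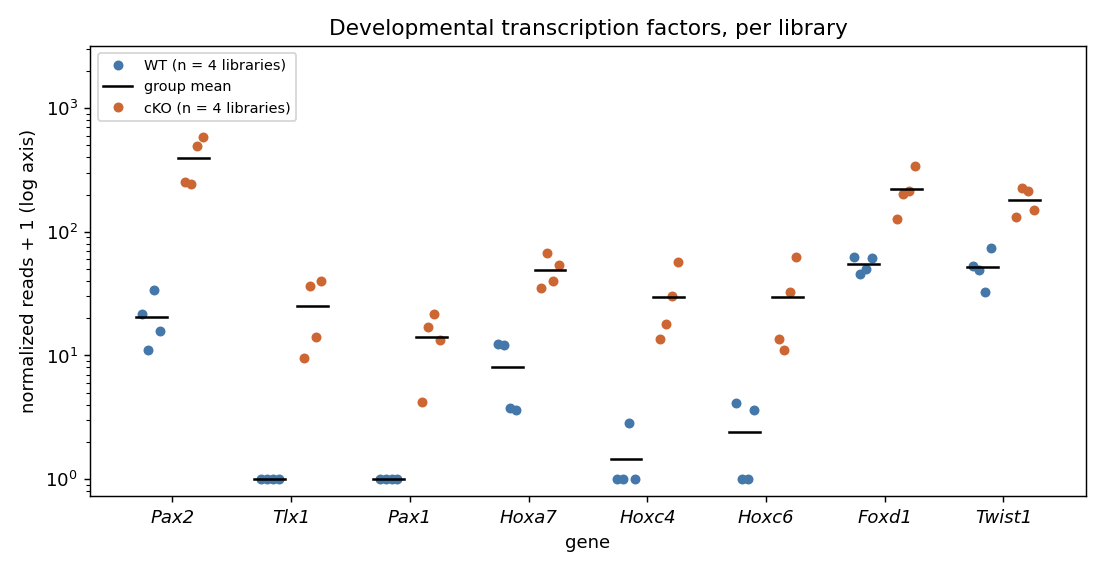
Normalized reads plus 1 (log axis) of 8 developmental transcription factor genes in each library, with WT in blue, cKO in orange, 4 libraries each, and a black bar at the group mean. Every cKO library lies above every WT library for each gene, and Tlx1 and Pax1 have 0 reads in all 4 WT libraries.

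Neuronal and circadian gene lists moved by small amounts at the median, though single protocadherin genes differed far more. Genes of the synaptic scaffold and vesicles rose as a list of 43 (35 with a positive log2 fold change, median 0.087, camera adjusted p = 1.00e-05), a call lost with an estimated correlation (adjusted p = 0.944 with an estimated correlation). Among them the vesicle protein gene Syp had 40991 ± 3985 normalized reads in WT and 51647 ± 3315 in cKO (SD, n = 4), and Nrxn2, a presynaptic adhesion gene, had 6893 ± 875 and 9149 ± 1362. Interneuron markers rose as a list of 21 (15 with a positive log2 fold change, median 0.11, camera adjusted p = 0.0389, adjusted p = 0.944 with an estimated correlation), with 5277 ± 246 reads in WT and 6380 ± 514 in cKO for the neuropeptide gene Sst. Clustered protocadherins, cell surface proteins many of which are spliced to shared end exons, rose as a list of 58 (42 with a positive log2 fold change, median 0.16, camera adjusted p = 0.00495, adjusted p = 0.944 with an estimated correlation). Within that list Pcdhga9 had 901 ± 706 and 8239 ± 4318, and Pcdhgb1 had 4417 ± 4372 and 305 ± 86.3. Reads in the shared exons can be assigned to several genes of the cluster, so these values are uncertain. Circadian clock genes rose as a list of 17 (14 with a positive log2 fold change, median 0.14, camera adjusted p = 0.000737, adjusted p = 0.395 with an estimated correlation), with Per1 at 2010 ± 269 and 2568 ± 231, and Clock at 5240 ± 708 and 4245 ± 347. The protocadherin call was lost without WT replicate 1 (adjusted p = 0.0630), WT replicate 2 (0.0812), cKO replicate 3 (0.129) or cKO replicate 4 (0.0625). The interneuron call was lost without WT replicate 1 (adjusted p = 0.248), WT replicate 2 (0.0812), cKO replicate 1 (0.0860), cKO replicate 3 (0.117) or cKO replicate 4 (0.342), and with quantile normalization (0.0987) or the stricter filter (0.0515).

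Oligodendrocyte, collagen, histone, choroid plexus and ependymal genes were the lists that fell. Oligodendrocyte markers fell as a list of 23 (22 with a negative log2 fold change, median −0.25, camera adjusted p = 0.000123, adjusted p = 0.944 with an estimated correlation), and 2 members passed adjusted over the list alone. Aspa, which breaks down N-acetylaspartate, had 840 ± 154 normalized reads in WT and 457 ± 74.6 in cKO (SD, n = 4), and the myelin genes Ermn and Opalin had 3404 ± 456 and 1371 ± 217 in WT against 2179 ± 589 and 844 ± 295 in cKO. Bcas1 was the 1 member with a positive value, 0.32 (SE 0.14). Collagens fell as a list of 44 (35 with a negative log2 fold change, median −0.37, camera adjusted p = 0.000172, adjusted p = 0.493 with an estimated correlation), with 1 member past adjusted over the list alone. Col11a2 had 1318 ± 193 reads in WT and 832 ± 136 in cKO, and Col5a2 had 465 ± 64.8 and 325 ± 40.1.

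Replication-dependent histone genes fell as a list of 60 (50 with a negative log2 fold change, median −0.33, camera adjusted p = 0.000398, adjusted p = 0.196 with an estimated correlation), with 1 member past adjusted over the list alone. Hist1h2ac had 147 ± 14.1 normalized reads in WT and 78.3 ± 7.50 in cKO (SD, n = 4), and Hist1h4h had 86.0 ± 8.85 and 59.8 ± 17.8. The mean log2 value of this list was 3.93 ± 0.12 in WT and 3.47 ± 0.16 in cKO, with no overlap between libraries (exact permutation p = 0.0286). For the synaptic, oligodendrocyte and choroid plexus lists the same measure overlapped between groups (exact permutation p = 0.257, 0.171 and 0.486). Several of these genes are near-identical copies, so the split of reads among them is uncertain.

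Choroid plexus markers fell as a list of 19 (18 with a negative log2 fold change, median −0.72, camera adjusted p = 0.0166, adjusted p = 0.944 with an estimated correlation), and ependymal markers as a list of 15 (13 with a negative log2 fold change, median −0.38, camera adjusted p = 0.0166, adjusted p = 0.944 with an estimated correlation). Both are tissues of the ventricle wall next to the hippocampus. Aqp1 had 477 ± 280 normalized reads in WT and 187 ± 129 in cKO (SD, n = 4), and the ciliary gene Dnah11 had 132 ± 68.5 and 59.4 ± 20.7. Ttr, the most abundant choroid plexus transcript, ranged from 3253 to 149458 between WT libraries and from 8208 to 42211 between cKO libraries. The choroid plexus call was lost without WT replicate 2 (adjusted p = 0.765), WT replicate 4 (0.197), cKO replicate 2 (0.0971) or cKO replicate 4 (0.302). The ependymal call was lost without WT replicate 2 (adjusted p = 0.402), WT replicate 4 (0.0615), cKO replicate 1 (0.0860), cKO replicate 3 (0.0609) or cKO replicate 4 (0.0516), and with the choroid plexus covariate (0.249).

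**Figure D3:**
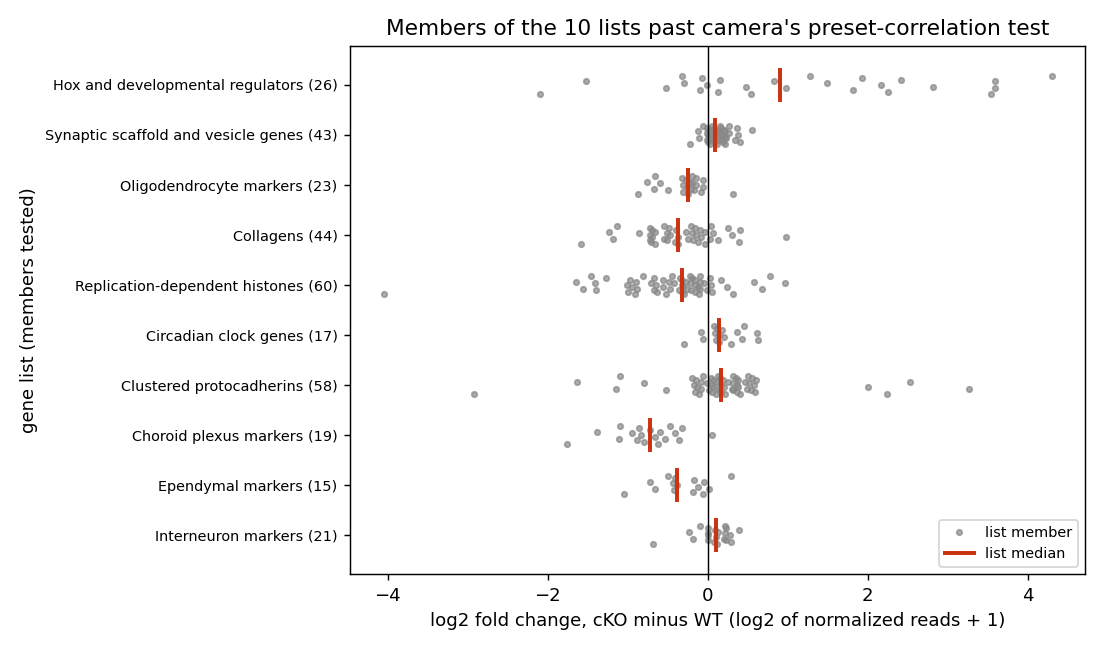
Log2 fold change (cKO minus WT, of normalized reads + 1) of each tested member, as grey points, of the 10 gene lists past camera with the preset correlation, with the list median as a red line and the number of tested members in brackets. The developmental regulators spread widest, with a median of 0.90, while the synaptic list lies close to 0, with a median of 0.087.

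Of 40 lists tested, 10 passed camera with the preset correlation of 0.01, 5 higher and 5 lower, and 0 passed with an estimated correlation, where 4 lists had an unadjusted p under 0.05. With fry, which asks whether a list moves on balance one way, 2 lists passed (developmental regulators and histones, adjusted p = 0.0465 for each), and 4 passed its test for change in either direction (developmental regulators, adjusted p = 0.000318; BRPF1 complexes, 0.00101; histones, 0.00268; circadian genes, 0.0331). The BRPF1 complexes hold the targeted gene Brpf1, the 1 member of that list past the threshold adjusted over the list alone. That list was not tested without Brpf1. Of the 1137 genes in the lists, 0 passed limma or limma-voom over all genes with all 8 libraries and no array weights, and 119 had an unadjusted limma p under 0.05. The synaptic, circadian, protocadherin, choroid plexus, ependymal and interneuron lists had 0 members past the threshold adjusted over the list alone.

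Markers of the principal neurons of the hippocampus and its surroundings did not pass. Median log2 fold changes were −0.055 for CA1 pyramidal markers (camera adjusted p = 0.992), −0.060 for CA3 and CA2 markers (0.763), −0.019 for dentate granule markers (0.700), 0.016 for cortical neuron markers (0.763), −0.20 for thalamic markers (0.149) and −0.032 for striatal markers (0.627). Glutamate receptors (camera adjusted p = 0.50), GABA receptors (0.681), voltage-gated channels (0.504), neuropeptides (0.149) and genes of chromatin-related intellectual disability (0.717) did not pass either. Nor did astrocyte markers (camera adjusted p = 0.326), reactive astrocyte genes (0.763), microglia markers (0.700), activated microglia genes (0.466), T cell and leukocyte genes (0.698), interferon-stimulated genes (0.763), oligodendrocyte precursor markers (0.698), endothelial markers (0.763), mural and fibroblast markers (0.763) or erythrocyte genes (0.681). Camera adjusted p was 0.717 for neurogenesis and cell cycle genes, 0.326 for p53 targets, 0.149 for unfolded protein and heat shock genes, 0.562 for cholesterol synthesis genes, 0.919 for ribosomal protein genes, 0.521 for mitochondrial genome genes and 0.0942 for nuclear oxidative phosphorylation genes. Immediate early genes, which respond to neuronal activity, did not pass as a list of 37 (camera adjusted p = 0.717), and 1 member passed adjusted over the list alone. That member was Inhba, an activin subunit gene singled out after its values were seen, with 616 ± 109 normalized reads in WT and 334 ± 80.2 in cKO (SD, n = 4). The CA3 and CA2 list also had 1 member past adjusted over the list alone, and the other lists that did not pass had 0, apart from the BRPF1 complexes above. For the dentate granule, GABA receptor, immediate early, neurogenesis, interferon, reactive astrocyte, endothelial, and mural and fibroblast lists the median, the mean and the camera direction differed in sign.

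Measures of the libraries themselves also differed between the groups. At least 1 read was found for 26918 ± 424 genes in WT and 26103 ± 472 in cKO (SD, n = 4), with every WT library above every cKO library (exact permutation p = 0.0286). After all libraries were thinned to the 40330226 reads of the smallest, the values were 26740 ± 328 and 26012 ± 443 (exact permutation p = 0.0286). A list of 27 transcripts known to be retained in the nucleus, chosen after the first fit, had a mean log2 value of 13.25 ± 0.074 in WT and 12.99 ± 0.19 in cKO (exact permutation p = 0.0857). The mitochondrial share of reads was 12.4% ± 1.51 in WT and 11.3% ± 0.914 in cKO (exact permutation p = 0.257). In a principal component analysis PC1 held 21.3% and PC2 18.6% of the variance, and cKO replicate 2 stood apart from the other libraries on PC2 at −49.8.

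**Figure D4:**
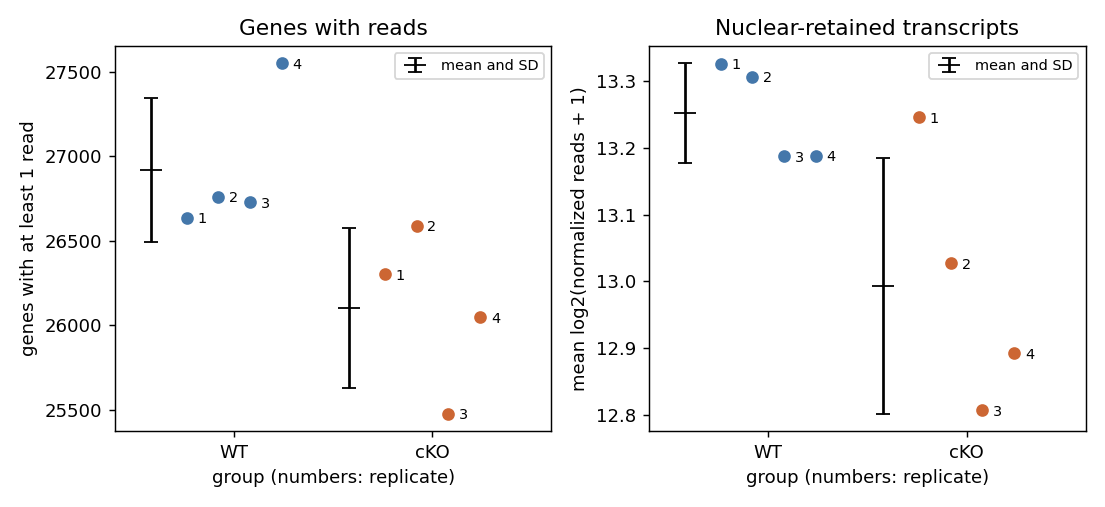
Genes with at least 1 read (left) and mean log2(normalized reads + 1) of 27 nuclear-retained transcripts (right) in each of the 4 WT and 4 cKO libraries, with points numbered by replicate and bars at the mean and SD; the axes do not start at 0. For genes with reads the groups do not overlap, and for the nuclear list cKO replicate 1, at 13.25, lies among the WT libraries.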

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

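Tests of fibroblast carry-over, of the Hox reads in WT replicate 1, of nuclear RNA and of depth were chosen after the values they use were seen. The hindbrain and neighbour tests were chosen after the first fit, but before the values of those lists were seen.

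Of 150 sets of 4 values examined, 7 held a library far from the other 3, where about 7.5 arise by chance. The gap to the nearest library, as a share of the whole range, was 1 for Chn1os1 in WT (reads in WT replicate 4 alone) and 1 for Hoxc4 in WT (reads in WT replicate 3 alone). It was 0.909847 for Pcdhga9 in cKO, where replicate 4 had 1854 normalized reads and the others 9642 to 11352, and 0.881498 for Jade2 in cKO, where replicate 4 had 3548. In WT it was 0.89455 for Sst and 0.837949 for Ttll6, both through replicate 1, and 0.863388 for genes with reads, through the 27549 genes of replicate 4.

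The developmental regulators were higher in cKO. Of 35 splits of the libraries, 1, the real one, gave a camera p as small (1.80e-07, against 1.74e-06 for the best of the others). That is the smallest share the design can give. The list was 1 of 40 tested, and the real split came first for 2 of these. The splits therefore do not exclude chance for this list. Its call was also lost with an estimated correlation (adjusted p = 0.196). Meningeal fibroblasts express Twist1 and Foxd1, but the 22 tested mural and fibroblast markers had a median log2 fold change of 0.044 and none exceeded 0.41, which argues against carry-over of that tissue; Ptgds had 12384 ± 5117 normalized reads in WT and 13187 ± 5848 in cKO. Hindbrain or spinal tissue, which expresses Hox genes, stays open: 10 tested markers had a median of −0.32 with an SD between markers of 0.88 and a highest value of 1.04, and most of them have few reads. In WT replicate 1, where the source of the Hox reads is unknown, 80.0% of Hoxb and Hoxc reads were Hoxb, against 10.8% in the cKO libraries (Fisher's exact p = 9.43e-33 over reads, which covers counting error only), which argues against the same source as the sole one of the Hox reads in cKO, though not as a part of it. Loss of Brpf1 in CA1 cells was not tested against these and remains open, as does carry-over from a tissue that was not listed.

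Nuclear transcripts and the number of genes with reads were lower in cKO. Depth is argued against, because after thinning to 1 depth the cKO libraries still had on average −728.2 genes relative to WT, with no overlap. A lower share of nuclear RNA may account for part of the pattern. A list of 27 nuclear-retained transcripts had a median log2 fold change of −0.27, with 26 of 27 lower. The list was chosen after the data were seen, so it is not independent evidence. Its camera p was 7.25e-11, but 0.104 with an estimated correlation, and per library the groups overlapped (exact permutation p = 0.0857). The histone list lay below every WT library in all 4 cKO libraries and the nuclear list in 3 of them, with cKO replicate 1 at 13.25 among the WT values, so whether the histone genes share that explanation is open. A change made by the knockout itself was not tested against a difference in extraction, and neither is excluded.

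The count of 5 changed genes was reached by 4 of 35 splits, the real one and 3 others, and the highest other split also gave 5, so chance is not excluded for the count. At an unadjusted p under 0.05, 3 of 35 splits, the real one included, gave at least the real 2266 genes, and the highest other split gave 3181. For gene lists 21 of 35 splits, the real one included, gave at least 10, and the highest other split gave 21. Chance is therefore not excluded for the number of lists, and why other splits give so many was not tested. List by list, the real split had the smallest camera p for the developmental regulators and the circadian genes (1 of 35 each), collagens and histones were next (2 of 35 each), and synaptic genes (7), oligodendrocyte markers (9), ependymal markers (10), interneuron markers (11), protocadherins (15) and choroid plexus markers (18) were reached or passed by many splits. Variants linked to Brpf1 are argued against as the source of the changed genes, since 1 of the 40 nearest tested genes had an unadjusted p under 0.05 (one-sided binomial p = 0.973), and the 5 genes lie on chromosomes 9, 16, 17 and 19 while Brpf1 lies on 6, but genetic differences elsewhere were not tested and stay open, and Nnt, Gm20431 and Gm45062 were high in some cKO libraries only.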

How the results depend on the processing

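The choroid plexus covariate and limma-voom were chosen after seeing the data, and the other settings before. Brpf1 had a negative log2 fold change under all 16 alternatives, from −0.53 to −0.63 when libraries were left out, and passed under none (adjusted p from 0.0619 to 0.484). The 5 changed genes became 2 with the replicate block (Aasdhppt and Pax2 remained, while adjusted p was 0.125 for Cbr1 and Robo3 and 0.107 for St6gal2), and 8 with array weights, all 5 among them. Without single libraries they numbered 4 to 7. The numbers do not pair the samples: same-numbered libraries deviated together with correlations of 0.035, 0.010, 0.059 and −0.018 over 16721 genes, and no WT library correlated best with its own number (the replicate block left 10 lists). The 10 gene lists became 0 with an estimated correlation, and 7 to 16 without single libraries, 16 without WT replicate 3. The cause of these shifts was not tested. Developmental regulators, circadian genes, collagens, histones, oligodendrocyte markers and synaptic genes passed under 15 of 16 alternatives, all but the estimated correlation. Protocadherins passed under 11, choroid plexus markers under 10, ependymal markers under 9 and interneuron markers under 8. With the choroid plexus covariate the choroid plexus list turned to the other direction (adjusted p = 0.854515), as the covariate is built from it.

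Genes in the list of BRPF1 complexes and related genes with values near 0 changed sign. With array weights Brpf3 had 0.0085, Ing5 0.033 and Jade3 −0.032. With the choroid plexus covariate Brpf3 had 0.033 and Jade3 −0.0065. With quantile normalization Ing5 had 0.0035 and Kat6a −0.0059. Without single libraries the ranges were −0.032 to 0.085 for Brd1, −0.10 to 0.081 for Brpf3, −0.067 to 0.056 for Ing5, −0.23 to 0.25 for Jade3, −0.045 to 0.10 for Kat6a and −0.069 to 0.028 for Kat6b. The cause was not tested. Depth limits genes with few reads, such as Hoxc4 with 2 reads in WT. The count tests planned for a table of raw counts were not run. limma-voom on the recovered reads stands in their place.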

Other observations

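Genes given here were singled out after their values were seen. The test of other transcription factors was set down before its first result, but the genes in it were changed after that result. Neat1, the scaffold of paraspeckles, had a log2 fold change of −0.74 (SE 0.10, adjusted p = 0.0714), and Xist had 64318 ± 4513 normalized reads in WT and 47692 ± 6270 in cKO (SD, n = 4). Neither passed limma over all genes. The glycolytic genes Gapdh (34319 ± 1826 in WT, 41683 ± 2028 in cKO) and Pkm (33744 ± 1309 in WT, 40167 ± 1710 in cKO) did not overlap between groups, and did not pass limma either (adjusted p = 0.382 and 0.428). Pou4f1, a homeobox gene of sensory neurons, had 21 reads in WT, all in replicate 4, and 29 to 57 reads in each cKO library (limma adjusted p = 0.291).

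Pax2 and Tlx1 lie close together on chromosome 19, with 8 tested genes between them in the GRCm38.p6 gene order. Those 8 genes had log2 fold changes from −0.21 to 0.22 and adjusted p of at least 0.590 in limma. Nnt, a mitochondrial transhydrogenase gene, had 100.4 to 159 normalized reads in the WT libraries and 729, 153, 1345 and 446 in cKO replicates 1 to 4. Its FDR in the authors' deposited table is 0.0236, while limma did not call it (adjusted p = 0.496). Gm20431 had 3399 reads in cKO replicate 1 and 0 in every other library, and Gm45062 had 327 in cKO replicate 1, 461 in cKO replicate 3 and 0 elsewhere; both have an FDR under 0.05 in the authors' deposited table.

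A hypothesis was that silent developmental transcription factors are released in cKO beyond the genes listed. Among other homeobox, paired box, T-box and forkhead genes, leaving out those already seen, 59 with a mean log2 value under 6 had a median log2 fold change of −0.088. That lies at percentile 85.99 of 10000 random lists matched on mean value, whose 90% range was −0.35 to −0.032, short of percentile 95, and camera did not set them apart from other genes (adjusted p = 0.866 over both sets tested). A first version of the set also took in antisense RNAs, pseudogenes and binding partners, 76 in all, and had a median of −0.35 at percentile 2.85, so the position depends on those members. A further 77 genes with higher values had a median of −0.050 at percentile 1.22, and camera, from limma, did not place them lower either (adjusted p = 0.813). Taken as whole sets, these remaining genes gave the hypothesis no backing, though the spread of the random lists leaves room for a small rise of the median. A median cannot show a release of a few members, so that stays open. Of the 59 genes, 27 had a positive log2 fold change, and single genes went both ways. Mean normalized reads in WT and cKO were 1.23 and 15.7 for Vax2, 0.864 and 5.84 for Nkx6-3, and 11.8 and 1.32 for Uncx. None of them passed limma over all genes. The genes left out as already seen include Pax2, Pax1, Tlx1 and Pou4f1, which were higher in cKO. The result therefore covers only the other genes and does not count against a release that includes those left out.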
